A study of Mus musculus with 2 samples.

How the data were processed

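DNase-seq data of thymus tissue from 2 B6CASTF1/J male mice aged 4 days were used. The labels give the samples as biological replicates 1 and 2 and name separate animals, while their donor identifier is the same. Both samples were placed in 1 group, thymus, and the replicate numbers were taken from the labels. For each sample, 2 peak lists, a footprint list and a list of positions with a false discovery rate were used. The peaks were derived from the filtered alignments of each library on mm10, per the README files deposited with the samples. They were therefore called per sample and not on pooled samples. The aligner, the peak caller, the footprint caller, their versions and the thresholds of the peak lists are not given in the sources used here.

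The deposited peak height was treated as a signal that is never negative. Its normalization by the authors is not stated. In the lower part of each list, up to the median height, 100% of the heights were whole multiples of 1 step per library within a tolerance of 0.05 of a step. The ratio of the steps was used as the relative depth, 1.65, which assumes that a step stands for 1 cut. The scale factor is not given in the sources used here. The depth therefore remains unknown, and heights were used to rank and describe peaks. The deposited footprint lists give the same value, 0.01, for every footprint, which was read as a q-value threshold and not as a measurement. The deposited false discovery rate lists hold q-values below 0.05 for runs of positions, per the README files and the values. They were derived by the authors from the alignments, and the tool is not given in the sources used here.

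The 2 peak lists of a sample differed in their threshold. Every peak of the longer list held a position with a listed q-value, and in the shorter list the lowest q-value of each peak was at most 0.001. By the rule fixed in advance the longer, less strict list was the main list and the stricter one an alternative. The reference was GRCm38, the genome of mm10, with GENCODE mouse release 21 annotation, from which 21851 protein-coding genes on the chromosomes were used. Coordinates are 1-based. The reference is that of the C57BL/6 strain, and sites where the CAST allele of the hybrids differs from it were not treated separately. Alleles were not analysed here.

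Peaks overlapping by at least 1 bp were called shared, and chance was measured with 100 circular shifts of the other replicate along each chromosome. A promoter peak lay within 1 kb of any start of a protein-coding gene. A distal peak of a gene lay in the gene body or within 10 kb on either side and over 1 kb from that gene's own starts, so a peak at the start of a neighbour counts as distal. Neighbouring peaks of a list can overlap, in 2008 cases in replicate 1 and 3061 in replicate 2, and each was counted. A total of 20 gene lists with 229 genes was fixed in advance. They covered T cell receptor complex, rearrangement, T lineage transcription factor, progenitor and mature T cell genes, 5 other blood lineages, 4 stromal types, 4 other tissues or states, housekeeping and cell division genes. All 229 genes were found in the annotation. Distal counts were compared with 10000 random lists of the same size matched on deciles of span, with a two-sided permutation p. Promoters were compared with two-sided Fisher's exact tests. Adjusted p-values are Benjamini-Hochberg values over the 20 lists, with a threshold of 0.05.

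A total of 30 consensus motifs was fixed in advance. Distal motif tests used the central 150 bp of shared peaks over 1 kb from any start and windows 1 kb to the side that overlap no peak. Footprint motif tests used 30 bp around the footprint centre and windows of the same peaks without a footprint. Both used two-sided Fisher's exact tests adjusted over the motifs, and a footprint motif was counted when its call was the same in both replicates. Matching on GC content used bins of 2 percentage points. A consensus match does not identify the protein bound.

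Genes were named by a rule fixed in advance. For a list that passed, up to 4 members with the most shared distal peaks were named, with every member without any if 3 or fewer. For a list that did not pass, up to 2 members with the most and up to 2 without any were named, with ties taken in list order. The 10 genes with the most shared distal peaks per 10 kb among those with at least 10, the 10 strongest shared peaks and a fixed set of loci were named too. The loci were Rag1, Rag2, Cd4, Cd8a, Cd8b1, Bcl11b, Tcf7, Ptcra, Cd3e, Cd3d, Cd3g, Foxn1 and Alb. Some genes and motifs that the rule or the tests cover are not reported here.

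The list test was tested on simulated data with 21851 genes and 20 lists, 3 of them changed, in 20 runs per fold. It recovered 16.7% of lists changed 2-fold and 48.3% of lists changed 3-fold, and called 0.294% and 0.882% of unchanged lists. The motif test was tested on 20000 windows with a motif planted in 5 percentage points of them. It recovered a difference of 4.94 percentage points and called 0 of the 29 other motifs. The simulated windows and their background had the same base composition, so the effect of a difference in GC content was not tested. Alternatives fixed in advance changed the peak list, the height threshold, the overlap, the list length, the windows, the span, the matching, the background and the replicates used. A further 8 alternatives, 5 for the distal test of the fixed lists and 3 for that of the added lists, were chosen after seeing the data. Software versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.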

Results

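Accessible chromatin was profiled by DNase-seq in the thymus of 2 male mice aged 4 days. In this assay the endonuclease DNase I cuts DNA that is not wrapped in nucleosomes, and sequenced cut positions mark accessible sites such as promoters and enhancers. The animals were of the strain B6CASTF1/J, a first-generation hybrid of a C57BL/6 and a CAST parent. The thymus is the organ in which T cell precursors rearrange their antigen receptor genes and are selected. The labels name thymus tissue and no sort, so thymocytes were measured together with stromal and other cells. The libraries formed 1 group of 2 biological replicates. The replicates were compared with each other, and gene lists, loci and sequence motifs were compared with matched controls within the libraries. Genes, peaks and sequence windows are not replicates, so the p-values given here describe these libraries and do not measure the spread between animals.

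The deposited lists held 97939 peaks in replicate 1 and 164634 peaks in replicate 2, a mean of 131286 ± 47160.5 (SD, n = 2). They also held 274179 and 491173 footprints, short stretches inside accessible DNA that are protected from cutting (mean 382676 ± 153438, SD, n = 2). The median peak was 180 bp wide and the median footprint 11 bp wide in both libraries. The total number of reads was not given in the sources used here. Up to the median height, 100% of the peak heights were whole multiples of 1 small step per library, 0.00603 in replicate 1 and 0.00366 in replicate 2, within 0.05 of a step. If a step stands for 1 cut scaled by depth, replicate 2 was 1.65 times as deep. On that reading the median peak rested on 147 cuts in replicate 1 and 159 cuts in replicate 2. Binomial intervals given below are exact 95% Clopper-Pearson intervals and cover counting error only.

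As lists, T cell receptor signalling genes and rearrangement and early thymocyte genes carried more distal peaks than random genes of the same span. The 18 genes of the T cell receptor complex, its co-receptors and proximal signalling held a mean of 9.94 distal peaks found in both replicates, 2.98 times the mean of matched random lists. The ratio was 3.02 in replicate 1 and 3.74 in replicate 2 (mean 3.38 ± 0.516, SD, n = 2). Shared distal peaks were most numerous at Cd8b1 with 28 and at the pan-T cell adhesion receptor Cd2 with 22. Peaks were counted as listed, so overlapping peaks, as at Cd8b1, are not separate sites. The receptor-proximal kinase Lck had 17 and the receptor zeta chain Cd247 had 15. In replicate 2 alone Cd247 had the most of the list, with 63, ahead of Cd8b1 with 51. The 11 receptor rearrangement and early thymocyte genes held a mean of 9.09, a ratio of 2.76 (3.36 and 2.90 in the replicates, mean 3.13 ± 0.319, SD, n = 2). Their members with the most were the chemokine receptor gene Ccr9 with 26, Notch1, the receptor whose signal commits precursors to the T lineage, with 17, the Notch target Dtx1 with 13 and Arpp21 with 12. The recombinase genes Rag1 and Rag2 had 3 each and Dntt had 4, where the random lists matched to this list had a mean of 3.29. All 18 and all 11 members had at least 1 shared distal peak. These 2 lists passed the permutation test of 10000 random lists, both at an adjusted p of 0.0300, and 15 and 10 of their members lay above the mean of random genes of their span. Such counts were also high in lists that did not pass, with 10 of 11 B cell genes and 11 of 12 housekeeping genes.

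The 15 transcription factors of the T lineage had a larger ratio, 3.26, but did not pass the same permutation test as designed (p = 0.0078, adjusted p = 0.0520). In the replicates the ratio was 3.36 and 3.72 (mean 3.54 ± 0.252, SD, n = 2), and 14 of the 15 members lay above the mean of random genes of their span. Tcf7, the factor that opens the T cell programme downstream of Notch, had 42 distal peaks. The test sat at its threshold for this list, since 14 of 20 other random seeds gave an adjusted permutation p under it, with a range of 0.0360 to 0.0600. With gene bodies alone in place of gene bodies plus 10 kb on each side, none of the 20 lists passed, and the adjusted permutation p was 0.0773 for the receptor complex list, 0.0640 for the rearrangement list and 0.0773 for the transcription factors. With 50 kb on each side the rearrangement list no longer passed (ratio 1.82, adjusted permutation p = 0.0533), whereas the transcription factors did (2.42, 0.049995). The transcription factors also passed in each replicate alone (adjusted permutation p = 0.0440 and 0.0333).

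The other 17 lists did not pass. Among blood lineages, the ratio was 1.67 for B cell genes (adjusted permutation p = 0.515), with 13 distal peaks at Ebf1, 12 at Pax5 and none at Ms4a1. It was 1.5 for mature single-positive and regulatory T cell genes (Itgae 12, Ccr7 8), and 1.15 for macrophage and granulocyte genes (Itgam 12, Spi1 6, none at Csf1r and Adgre1). It was 1.1 for uncommitted progenitor genes (Lyl1 10, Meis1 8, none at Hhex) and 1.03 for dendritic cell genes (Flt3 9, Xcr1 5, none at Siglech). For NK and innate lymphoid genes it was 1.02 (Klrb1c 5, Id2 5, none at Ncr1 and Klrd1), and for erythroid genes 0.974 (Ank1 8, Klf1 6, none at Hbb-bs and Alas2).

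Among stromal lists, the ratio was 0.697 for cortical and general thymic epithelial genes, with 5 distal peaks each at Ly75 and at the Notch ligand gene Dll4 and none at Epcam and Eya1. It was 1.12 for medullary thymic epithelial genes (Cd80 9, Tnfrsf11a 5, none at Ccl21a and Cldn3). It was 1.09 for endothelial genes (Pecam1 15, Erg 10, none at Tek and Emcn) and 0.765 for mesenchymal genes (Pdgfrb 5, Col1a1 5, none at Col3a1 and Dcn). For genes of other tissues it was 0.556 in hepatocytes (Hnf4a 4, Fgb 3, none at Alb and Serpina1a), 1.45 in neurons (Rbfox3 24, Tubb3 17) and 1.11 in muscle (Ckm 7, Tnnt2 4, none at Myf5 and Actc1). It was 0.702 for pluripotency and germline genes (Pou5f1 5, Esrrb 3, none at Zfp42), 1.61 for housekeeping genes (Ywhaz 7, Actb 6) and 0.963 for cell division genes (Mcm2 6, E2f1 5, none at Ccna2 and Plk1). The lowest adjusted permutation p among these 17 lists was 0.515. In simulated data the test recovered 16.7% of lists raised 2-fold and 48.3% of lists raised 3-fold, so a list that did not pass was not shown to be like other genes.

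**Figure D1:**
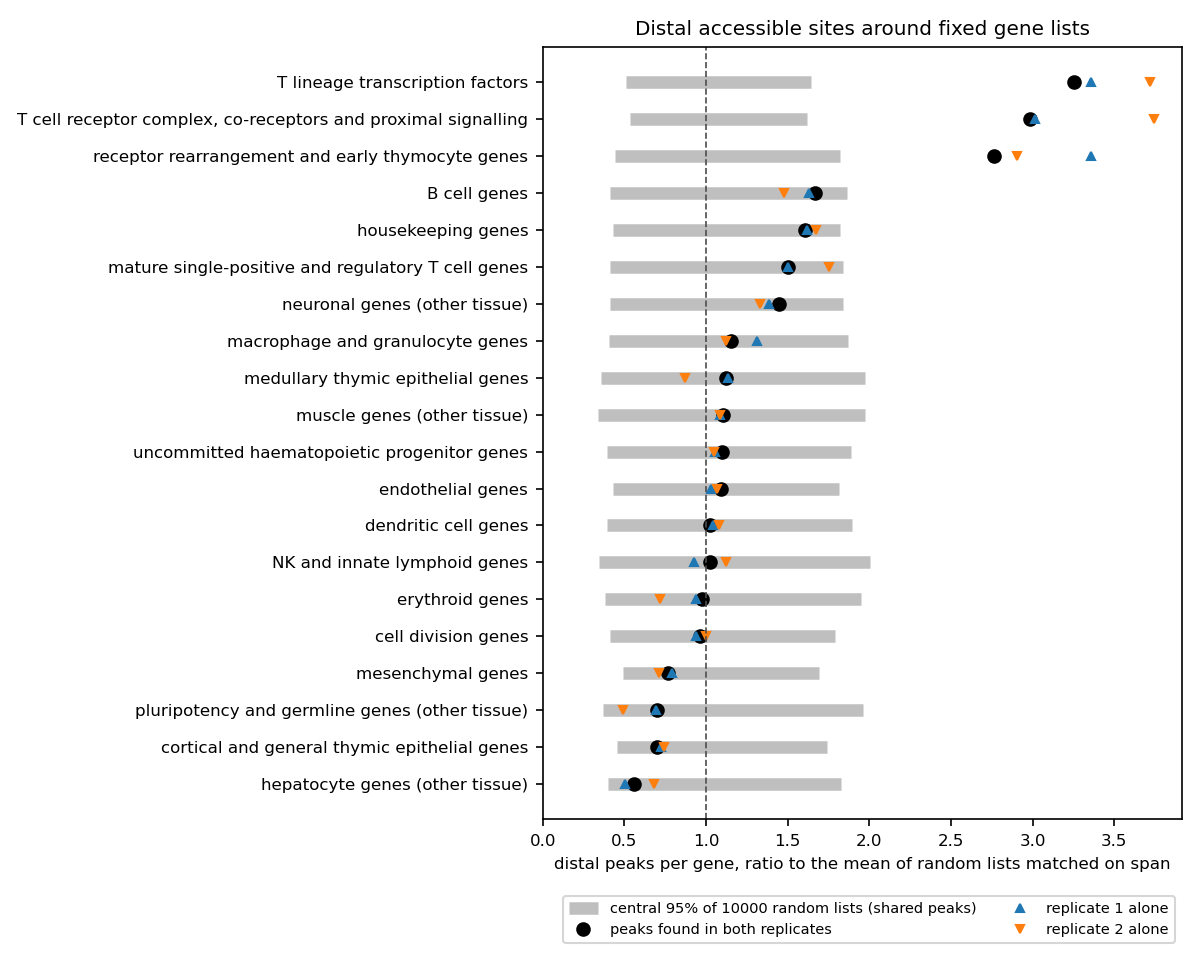
Distal peaks per gene around the 20 fixed gene lists, as the ratio to the mean of random lists matched on span (horizontal axis, linear, no unit). Black points are peaks found in both replicates, triangles are each replicate alone, and grey bars are the central 95% of 10000 random lists; the 3 T cell programme lists lie to the right of their bars at 3.26, 2.98 and 2.76.

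The loci chosen in advance had their strongest accessible sites at different distances from the start of the gene (mm10 coordinates). At Rag1, which encodes a subunit of the receptor recombinase (chromosome 2, 101638282 to 101649501, minus strand), the strongest peak lay 3.5 kb upstream at 101652961 to 101653140 in replicate 1, with a height of 7.63 there and 15.8 in replicate 2. Rag2, its partner gene (chromosome 2, 101624718 to 101632529, plus strand), had its strongest peak over its start in the UTR, with heights of 3.31 and 4.51. At the co-receptor gene Cd4 (chromosome 6, 124864692 to 124888221, minus strand) the strongest peak lay beyond the end of the gene, 28.3 kb downstream of the start at 124859821 to 124860020, with heights of 14.4 and 16.6. No peak lay within 1 kb of a Cd4 start in replicate 1, and in replicate 2 the highest of 3 such peaks had a height of 1.57.

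At Cd8b1 (chromosome 6, 71322788 to 71337494, plus strand) and Cd8a (chromosome 6, 71373427 to 71379173, plus strand), which encode the other co-receptor, the strongest peaks lay at the starts. Their heights were 6.22 and 13.5 at Cd8b1, where a start of Smyd1 also lies within 1 kb, and 4.26 and 7.26 at Cd8a. Cd8b1 had 31 peaks in replicate 1 and 53 in replicate 2 over the gene and 10 kb on each side. At Bcl11b (chromosome 12, 107910403 to 108003602, minus strand), a transcription factor required for T lineage commitment, the strongest peak was intronic, 4.7 kb from the start at 107998861 to 107999020, with heights of 11.5 and 19.0. At Tcf7 (chromosome 11, 52252371 to 52283014, minus strand) it lay 0.4 kb upstream of the start, with heights of 4.47 and 8.28, among 52 peaks in replicate 1 and 70 in replicate 2.

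**Figure D2:**
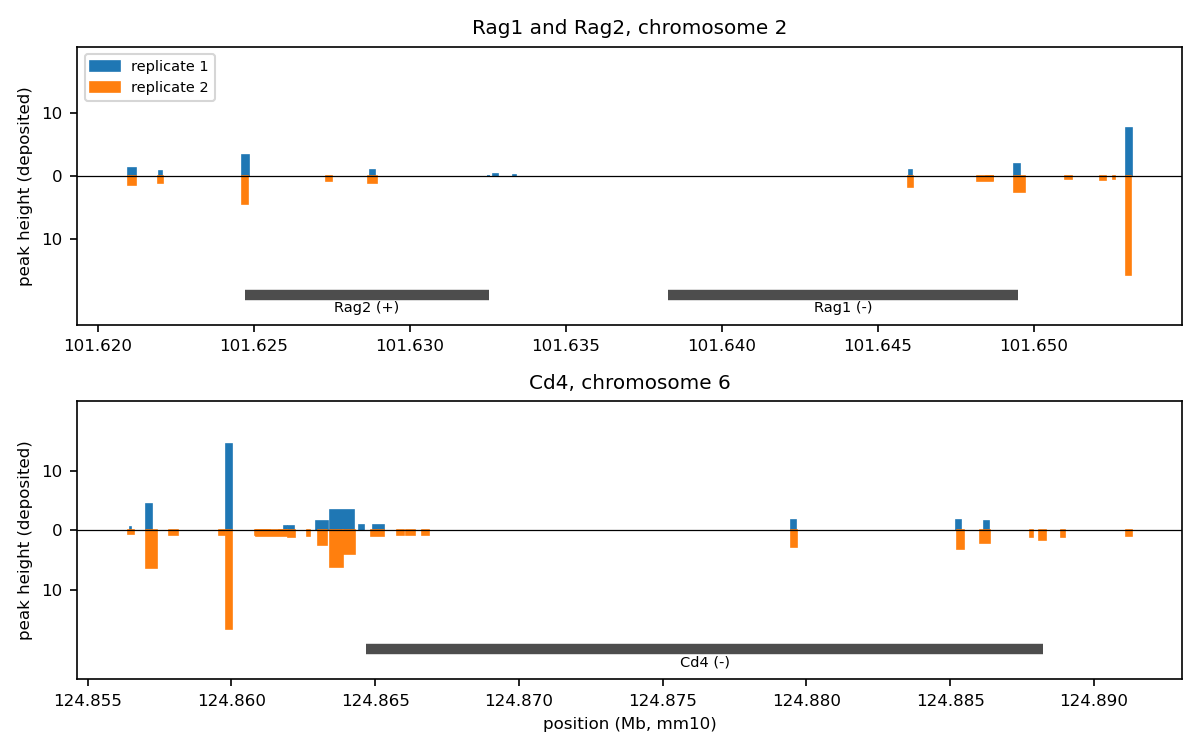
Peaks at Rag1 and Rag2 on chromosome 2 and at Cd4 on chromosome 6 (horizontal axis, position in Mb on mm10; vertical axis, deposited peak height), with replicate 1 drawn upward, replicate 2 drawn downward and dark bars for the genes. The tallest bars are the site upstream of Rag1 (7.63 and 15.8) and the site beyond the end of Cd4 (14.4 and 16.6).

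Within 10 kb of some T cell genes the strongest peak lay at the start of a neighbour. The strongest peak near Cd3g (chromosome 9, 44969572 to 44980431, minus strand) had heights of 23.0 and 31.8 and lay at the start of Ube4a, and the strongest away from any start lay 13.4 kb downstream of the Cd3g start, with heights of 5.66 and 8.56. The strongest peak near Cd3d (chromosome 9, 44981786 to 44987339, plus strand) was that at the start of Cd3g, with heights of 4.88 and 9.11. At Cd3e (chromosome 9, 44998740 to 45009627, minus strand) the strongest lay 1.1 kb upstream, with heights of 3.14 and 4.98. The strongest peak near Ptcra (chromosome 17, 46755663 to 46763712, minus strand), which encodes the pre-receptor alpha chain, had heights of 9.56 and 19.1 and lay at the start of Cnpy3. The strongest away from any start lay 4.3 kb upstream of Ptcra, with heights of 2.74 and 4.70.

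The thymic epithelial regulator Foxn1 (chromosome 11, 78357577 to 78386558, minus strand) had 4 peaks in replicate 1 and 6 in replicate 2, none within 1 kb of its starts. Its strongest peak was intronic in both, 26.3 kb from the start in replicate 1 (height 5.79) and at another position, 25.9 kb from the start, in replicate 2 (height 9.43). The liver gene Alb (chromosome 5, 90460897 to 90476602, plus strand) had no peak in replicate 1 and 1 in replicate 2, 7.9 kb upstream with a height of 0.238.

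The protein-coding genes with the most shared distal peaks per 10 kb of span, among those with at least 10 such peaks, were led by Tap2, which encodes a subunit of the antigen peptide transporter, with 10.7 per 10 kb. Gpr132 had 10.4, Smim5 9.88, Tapbpl 9.31, Phospho1 9.04, Abi3 8.33, Tcf7 8.29, Lgals3bp 8.18, Cd8b1 8.07 and Ly6e 8.05. Phospho1 and Abi3 overlap on chromosome 11 and share peaks. Away from the starts of all protein-coding genes these 10 genes kept between 19 peaks (Ly6e) and 42 peaks (Tcf7).

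Accessible promoters were more frequent in 3 of the lists and less frequent in 2. All 15 T lineage transcription factors had a peak within 1 kb of a start in both replicates, against 65.3% of other protein-coding genes (adjusted p = 0.0210, two-sided Fisher's exact test over 20 lists). All 12 housekeeping genes and all 12 cell division genes did so too (adjusted p = 0.0450 each, Fisher's exact test). The share was lower for hepatocyte genes, with 1 of 10 (adjusted p = 0.01, Fisher's exact test), the exception being Apob, which was singled out after its values were seen. It was also lower for muscle genes, with 2 of 10 (adjusted p = 0.0302, Fisher's exact test). In replicate 2 alone the adjusted Fisher's exact p was 0.0559 for the transcription factors and 0.0932 for housekeeping and for cell division genes. All members of these 3 lists still had a promoter peak there, but so did 70.0% of all protein-coding genes. Muscle genes, with 4 of 10 there, had an adjusted Fisher's exact p of 0.151. The 1 list that passed as higher was the receptor complex genes, at an adjusted Fisher's exact p of 0.0305. With a 2 kb window none of the 20 lists passed, and among these 5 the adjusted Fisher's exact p ranged from 0.0594 for the 3 higher lists to 0.1997 for muscle genes.

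The remaining lists did not pass. Macrophage and granulocyte genes had 4 of 13 promoters accessible (adjusted p = 0.0524, Fisher's exact test), erythroid genes 4 of 11 and dendritic cell genes 4 of 9. Receptor complex genes had 16 of 18, lacking Cd4 and Ptprc, whose promoter peaks were called in replicate 2 alone. Rearrangement genes had 10 of 11, progenitor genes 9 of 9, mature T cell genes 9 of 11 and B cell genes 6 of 11. NK and innate lymphoid genes had 5 of 10, cortical epithelial genes 9 of 14, medullary epithelial genes 6 of 10, endothelial genes 6 of 10 and mesenchymal genes 8 of 13. Neuronal genes had 9 of 10, and pluripotency and germline genes 5 of 10.

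Promoters held more of the peaks than their share of the genome. Windows of 1 kb around protein-coding starts covered 1.97% of the genome and held 29.2% of the peaks in replicate 1 (interval 28.9 to 29.5) and 21.1% in replicate 2 (interval 20.9 to 21.3), a mean of 25.1% ± 5.69 (SD, n = 2). Introns held 31.7% and 35.8%, exons 4.71% and 5.92%, and sequence outside protein-coding genes 34.5% and 37.2%. Among peaks found in both replicates, those at promoters had a median height of 1.89 in replicate 1, against 0.862 in introns and 0.856 outside protein-coding genes. Of the 1000 strongest shared peaks, 90.0% lay at promoters, against 30.2% of all 86752.

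The 10 strongest shared peaks included the promoters of Dynlt1b (heights 72.0 and 99.2), Mplkip (41.1 and 82.9), Myo10 (44.3 and 71.2), Nup107 (39.7 and 71.6) and Faim (34.5 and 63.1). A further 3 lay outside protein-coding genes but near other annotated starts, at 27 bp from that of the pseudogene 2610005L07Rik (50.2 and 78.5), 117 bp from the non-coding Gm42418 (62.5 and 63.8) and 664 bp from the non-coding Gm27940 (37.6 and 55.0). Another lay in an intron on chromosome X, 11202 bp from the nearest start, that of the antisense gene Gm15247 (43.9 and 68.2). The last lay in an exon, 16705 bp from the nearest start, that of Limd1 (49.99 and 61.9). In 5 of the 10, at least 50% of the 32-mers occur more than once in the reference genome, so their heights are uncertain. These are the peaks nearest to the starts of Dynlt1b, 2610005L07Rik, Gm42418, Gm15247 and Limd1.

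Distal accessible sites were rich in sequences bound by CTCF, the insulator protein, and by the ETS, E protein, MYB and RUNX families. The central 150 bp held a CTCF consensus in 10.1% of the 56429 distal shared peaks tested. Windows 1 kb to the side held it in 0.0379%. Its odds ratio was 297 (interval 191 to 460.5), and 245 and 182 with the peaks of replicate 1 or 2 alone. In shared peaks the odds ratio was 3.70 for ETS (interval 3.39 to 4.04) and 2.26 for the E protein site of E2A and HEB (2.17 to 2.35). For MYB it was 1.75 (1.58 to 1.95) and for RUNX 1.48 (1.40 to 1.56). The PU.1 consensus, an extended ETS site, stood at 4.40. SP/KLF sites stood at 11.9 and CRE/ATF at 3.68. NRF1 stood at 11.4 (11.7 and 7.60 with replicate 1 or 2 alone) and REST at 6.06 (5.35 and 3.22). AP-1, EBF and GRHL sites were also higher, at 1.246, 1.34 and 1.99. TCF7/LEF1 sites did not differ as designed (odds ratio 0.903, adjusted p = 0.229, Fisher's exact test), and were lower with the stricter peak list (0.770).

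In all, 14 of the 30 motifs were higher and 7 lower by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment. The lower motifs were NFAT (0.495), MEF2 (0.598), IRF/ISRE (0.604), GATA (0.668), OCT (0.679), IKZF (0.821) and TEAD (0.846). The distal peaks were richer in G and C than the background (53.7% against 45.5%). Against windows matched on GC content, 14 motifs were higher and 3 lower, of which 12 and 2 had the same call in both settings. CTCF (302), ETS (2.66), RUNX (1.73), MYB (1.52) and E protein sites (1.42) kept their calls. SP/KLF stood at 4.08 and NRF1 at 6.41. The calls ended for NFAT (0.978), GATA (0.931), IRF/ISRE (1.07), MEF2 (1.02), EBF (0.962) and GRHL (1.78), and OCT turned to higher (1.34, adjusted p = 0.0117, Fisher's exact test). CEBP sites were newly called higher (1.57, adjusted p = 0.0368) and NF-kB sites newly lower (0.603, adjusted p = 0.0328, Fisher's exact tests). Among the calls that ended with 1 library alone were TEAD in both (0.869 and 0.922) and GRHL in replicate 2 (1.54).

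**Figure D3:**
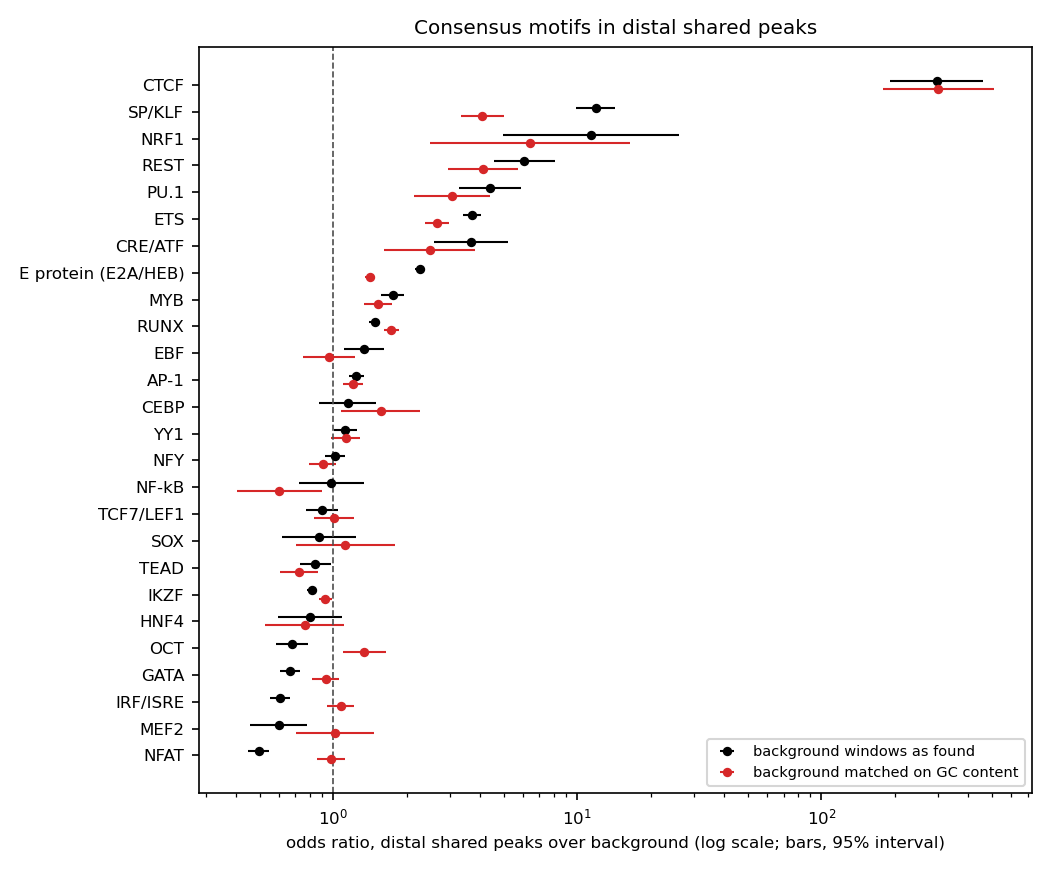
Odds ratio of a consensus match in distal shared peaks over background windows for motifs fixed in advance (horizontal axis, log scale, no unit), with 95% intervals as bars; HNF1 and GRHL, which had few matches, are among those not drawn. Black points use windows as found and red points windows matched on GC content. CTCF stands apart at 297 and 302, and OCT lies on opposite sides of 1 at 0.679 and 1.34.

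Relative to footprint-free windows, protected positions were most enriched in the sequences of CTCF and NRF1, a regulator of nuclear genes for mitochondrial proteins. In 30 bp windows centred on footprints, the CTCF consensus was enriched over footprint-free windows of the same peaks with an odds ratio of 126 in replicate 1 and 99.1 in replicate 2 (mean 113 ± 19.4, SD, n = 2). NRF1 was at 57.1 and 16.0 (mean 36.5 ± 29.1, SD, n = 2), SP/KLF at 9.79 and 10.3, CRE/ATF at 9.40 and 7.94 and REST at 4.12 and 4.20. NRF1 sites were rare, in 0.167% and 0.112% of footprint windows, and only 7 and 28 background windows held one. YY1, NFY, ETS and IKZF sites were enriched to a smaller degree, with mean odds ratios of 2.06, 1.76, 1.29 and 1.27. These 9 motifs were higher in both replicates, and 6 were lower in both, among them GATA (mean 0.556), AP-1 (0.755), PU.1 (0.757), IRF/ISRE (0.774) and E protein sites (0.914). With GC-matched windows the lower calls of PU.1 (mean 0.864) and IRF/ISRE were among those that ended, and IRF/ISRE did not pass in replicate 1 (0.880) but turned to higher in replicate 2 (1.16, adjusted p = 0.0184, Fisher's exact test).

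CTCF matches inside peaks overlapped a footprint in 96.1% of cases in replicate 1 (6106 of 6356, interval 95.6 to 96.5) and 96.2% in replicate 2 (6873 of 7141, interval 95.8 to 96.7). For NRF1 the shares were 94.8% and 91.8%. RUNX matches overlapped a footprint in 29.0% and 29.9%, and TCF7/LEF1 matches in 31.2% and 35.2%. The share that the density of footprints alone would give was not measured. RUNX sites were enriched in footprints in replicate 2 (odds ratio 1.11, adjusted p = 5.70e-05) but not in replicate 1 (1.03, adjusted p = 0.481, Fisher's exact tests), and with GC-matched windows they were higher in both (1.21 and 1.37). TCF7/LEF1 sites were enriched in replicate 2 (1.42) and not in replicate 1 (0.910). The difference between the replicates was not tested for either motif.

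The replicates shared most of their strong sites. Of the peaks of replicate 1, 88.6% overlapped a peak of replicate 2 (interval 88.4 to 88.8), against 2.41% after circular shifts along the chromosomes. Of the longer list of replicate 2, 52.6% overlapped a peak of replicate 1, against 1.46% by chance. Peaks of replicate 1 were found again in 41.5% of cases in the lowest decile of height and in 99.8% in the highest decile. Footprints were shared to a lower degree, 74.2% of those in replicate 1 and 38.6% of those in replicate 2, against chance values of 0.534% and 0.301%. Within shared peaks, 76.3% of the footprints of replicate 1 overlapped one of replicate 2, against 46.6% after a shift of 50 bp. Of all footprints, 87.0% in replicate 1 and 81.5% in replicate 2 lay inside peaks (mean 84.3% ± 3.90, SD, n = 2).

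Across the 86752 shared peaks, which are not independent replicates, heights correlated with a Pearson r of 0.974 on the log10 scale and a Spearman rho of 0.972. Heights were greater in replicate 2 for 82.5% of the shared peaks, with a median log2 ratio of 0.43, or 1.35-fold. The median log2 ratio ran from -0.20 in the lowest decile of height to 0.73 in the highest decile. These ratios assume that the deposited heights of both libraries are on the same scale, which the sources do not state. Shared peaks had to be called in both libraries, and the lowest listed height was 0.0422 in replicate 1 and 0.0146 in replicate 2. Whether this selection lowers the ratio in the lowest decile was not tested. With 2 libraries in 1 group, no test between the animals was possible.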

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

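The 5 alternatives added for the distal test of the fixed lists and the 3 for that of the added lists were chosen after seeing the data, and all others before the data were examined. Of the values that answer a comparison, 43 stayed on their side of the threshold or within the spread of the replicates or 1.5 times the count, and 11 moved. The shares of footprints inside peaks and of peaks at starts could not move with a replicate left out. Each of 2 values always lies within their SD of the mean. The share of shared peaks had a wide SD, 25.4 percentage points, so it could hardly move. The 43 thus include values that could not have moved. With the top height-ranked part of each list (0.5 of the peaks) the mean was 65643 peaks and with the stricter list 84823, fewer by construction. The share of footprints inside peaks was then 61.0% and 67.9%, also because fewer peaks were kept. The share of peaks at starts was 34.9% and 31.7%. Promoter peaks were taller than intronic ones (median height 1.63 against 0.772 in replicate 1 and 1.66 against 0.541 in replicate 2). A choice by height therefore favours promoter peaks. For the stricter list the cause was not tested. The rank correlation was 0.974 with reciprocal overlap and 0.956 in the top part, and the cause was not tested. The number of lists with more distal peaks was 0 with gene bodies only, and that with more promoter peaks was 0 with a 2 kb window. The latter ran from 1 to 3 with a replicate left out, and the 1 list called without replicate 1 was none of the 3 main ones. Without replicate 1 all members of those 3 lists kept a promoter peak, while the share of all protein-coding genes with one was 70.0%. That share was 65.3% in both replicates. Other causes were not tested.

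Among motifs called with windows as found, GC matching moved the distal odds ratio to the other side of 1 for IRF/ISRE (1.07), EBF (0.962), OCT (1.34) and MEF2 (1.02), and the mean footprint odds ratio for IRF/ISRE (1.02, from 0.880 and 1.16 in the replicates). Of these, OCT passed the test, and so did the footprint value of IRF/ISRE in replicate 2 alone (adjusted p = 0.0184, Fisher's exact test). The cause beyond the matching was not tested. Of the other values for single lists, motifs and genes, 614 were on the same side, 107 moved, 42 newly passed and 29 no longer passed. The T lineage transcription factors newly passed with 100000 random lists (adjusted permutation p = 0.0431), without 7 random genes over 2 Mb (0.0020), without peaks at other genes' starts (0.0333), with replicate 1 alone (0.0440) and with replicate 2 alone (0.0333). They also newly passed with 50 kb on each side, the top part by height, equal list lengths and no matching on span (0.0227 to 0.049995). They did not pass with the stricter list (0.0573), random genes that have a promoter peak (0.0613) or gene bodies only (0.0773). These genes do not overlap each other with 10 kb on each side, so counting overlapping members once (0.0520) repeated their main test. In that setting all 20 lists kept their calls. Over all alternatives the ratio of the transcription factors ran from 2.42 to 4.96. An equal number of footprints was not run, because the footprint list gives no score to rank by. No paired analysis was possible because there is 1 group. Of the peaks of replicate 1 in the lowest decile of height, 41.5% were found again, and whether read depth limits this was not tested.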

Other observations

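The lists outside the fixed set were drawn up after the results of the fixed lists were known, and the tests of the class I list, of the added lists without the member with the most peaks, of the number of peaks and of the height shifts were chosen only after the results they address were seen. The tests of repeated sequence and of the other 3 added lists were set beforehand.

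Genes that T cell receptor signals induce carried many distal accessible sites in this tissue, for which the labels name no stimulation. The 11 receptor-induced genes held a mean of 9.27 shared distal peaks, 3.92 times the mean of matched random lists (two-sided permutation p = 0.0002, the smallest the permutations can give, and adjusted p = 0.0008 over 4 lists), led by Irf4 with 20, the phosphatase gene Dusp2 with 14, Junb with 13 and Nfatc1 with 12. The 10 genes of thymocyte apoptosis and survival held 2.32 times the mean (permutation p = 0.0114, adjusted p = 0.0228 over the same 4 lists). Adjusted values over 4 lists cannot be compared with those over the 20 fixed lists, where a permutation p of 0.0078 did not pass. The apoptosis and survival genes had 12 peaks at Bcl2l11, which encodes the BIM protein, 11 at Bcl2 and 10 each at Bbc3 and Bid. All members of both lists had a promoter peak in both replicates and at least 1 distal peak. The random lists drew on all protein-coding genes, of which 65.3% had a promoter peak in both replicates. A comparison with random genes that have a promoter peak was not run for the added lists. Without Irf4 the receptor-induced genes still passed (ratio 3.51, adjusted permutation p = 0.0008). Without Bcl2l11 the apoptosis and survival genes had a ratio of 2.16 and did not pass (adjusted permutation p = 0.0528), although away from the starts of all protein-coding genes they did (2.53, 0.0332). Which cells of the tissue carry these sites was not tested.

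Class I antigen processing genes other than Tap2, Tapbpl and the neighbours of Tap2 had a ratio of 1.46 (adjusted p = 0.263, permutation test), and 0.807 away from the starts of all protein-coding genes. Tapbp held 13 of the 34 distal peaks of this list, and without it the ratio was 1.02 (adjusted p = 0.960, permutation test). The test neither found nor excluded that the dense sites around Tap2 and Tapbpl extend to the rest of that pathway. Chemokine receptor genes other than Ccr7 and Ccr9, which belong to fixed lists and had 8 and 26 distal peaks, had a ratio of 1.62 (adjusted p = 0.152, permutation test), with 21 peaks at Cxcr5 and none at Ccr1, Cxcr2 and Cxcr3. Away from all starts the ratio was 2.14 (adjusted p = 0.0475, permutation test), so that result depends on how neighbouring promoters are counted. Within this reduced list it also depends on 1 gene, since Cxcr5 held 21 of the 46 distal peaks of the list, and without it the ratio was 0.994 (adjusted p = 0.960), and 1.25 away from all starts (adjusted p = 0.625, permutation tests).

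The antigen receptor constant genes differed in their sites. Within 10 kb of Trac, the receptor alpha constant gene, replicate 1 had 12 peaks and replicate 2 had 27, with highest heights of 9.03 and 16.2. Trdc had 15 and 29 peaks (6.08 and 7.43), Trbc1 8 and 28, and Trbc2 11 and 31, the last pair sharing a highest peak of 2.48 and 3.35. The immunoglobulin heavy constant gene Ighm had 14 and 17 peaks (1.34 and 1.85), whereas the light chain gene Igkc had 2 in each (0.301 and 0.424). No peak was listed near Tcrg-C1, Tcrg-C2 or Tcrg-C3 in either replicate, and Tcrg-C4 had 4 and 7. These values were not tested. Repeated sequence was not checked at these genes or at those of the gene lists, so a missing peak there does not show a closed site.

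Replicate 2 held more peaks than replicate 1. Depth alone would leave the heights of shared peaks equal if they are scaled by depth. The median log2 ratio of shared peaks was 0.43, from -0.20 in the lowest decile of height to 0.73 in the highest. How far the choice of peaks called in both libraries sets the low end was not tested. The scale is not stated in the sources used here and 1 library was compared with 1 other, so depth as the whole cause stays open. A larger share of cuts in accessible sites in replicate 2 stays open, because the summed heights over the same shared peaks, 1.54 times as large in replicate 2, follow from those ratios and do not test it. Library preparation and a difference between the animals stay open and were not tested.

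The heights did not shift alike everywhere: relative to the median, NFY-containing promoters stood higher in replicate 2 and CTCF sites lower. The log2 shifts were 0.42 and -0.06. After subtracting the median of peaks of the same height, the shift at NFY promoters shrank to 0.18 and that at CTCF sites grew to -0.18, so height may account for much of the former and not of the latter. With GC content of the central 150 bp matched as well they were 0.14 and -0.09, over 0.05 in size on 18 and 17 of 20 chromosomes. The NFY shift argues against height or GC content, so measured, as the whole cause. GC content of wider sequence was not matched and stays open. With place also matched, the shifts shrank to 0.08 at NFY promoters and -0.06 at CTCF sites, over 0.05 in size on 14 and 11 of 20 chromosomes, so a general difference between promoters and other sites may account for part of them. A larger dividing fraction in replicate 2 stays open, since cell division promoters lay at the 92.6th percentile of matched random promoters, between the bounds set for the test. A different makeup of cell types stays open too. Of the 20 lists, 4 had a median shift outside the central 95% of matched random sets, where chance gives about 1 for independent peaks. Erythroid, neuronal and muscle genes were low and cell division genes high. The random peaks were drawn singly over the genome, whereas those of a list cluster around its genes, so chance may give more.

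The strongest shared peaks may in part be reads from repeated sequence. In 5 of the 10, at least 50% of the 32-mers occur more than once in the reference genome, against 0 of 10 peaks just below rank 10000 in height. For 4 of the 10, at Mplkip, Myo10, Nup107 and Faim, no 32-mer occurs more than once, so the reference offers no second copy for them. That number lay between the bounds set in advance, so repeated sequence is neither excluded nor sufficient for the set as a whole. Copies missing from the reference or specific to CAST were not tested, and no biological explanation was tested.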
